A study of Mus musculus with 8 samples.

How the data were processed

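RNA from primary mouse astrocyte cultures was measured on 8 Agilent 1-colour arrays. Per the labels' protocols, the cells came from brains of male and female B6129 pups at postnatal day 3 to 4, grew for 2 weeks in medium with 10% serum, were replated in 12-well plates and were treated within 1 week. The groups were 4 samples treated with alphaD11, an antibody against nerve growth factor (NGF), 2 samples treated with an antibody against the V5 tag, and 2 untreated (naive) samples. Both antibodies were given at 100 ng/ml, and RNA was taken at 24 hours. Per the labels' protocols, samples with an RNA integrity number below 8.0 were discarded and 200 ng of RNA per sample was labelled with Cy3.

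The deposited scanner files hold 1 spot intensity per feature on a linear scale, written by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09, per the file headers. The processed signal in them is background-subtracted and detrended by that software, and the files hold no mean spot signal and no gene names. The authors also deposited a table of log2 values for 31162 probes. Each of its columns equalled log2 of that array's processed signal plus 1 constant per array, within 0.001 for 99.7% to 99.8% of the probes, and the 75th percentile of every column was 11.04. Its column medians were 8.68, 8.65, 8.68 and 8.68 for alphaD11 replicates 1 to 4, 8.61 and 8.60 for the anti-V5 samples, and 8.63 and 8.64 for the naive samples. The scale and centring of that table are therefore known from this comparison, and how its probes were chosen is not given in the sources used here, although 31154 of them were well above background on all 8 arrays. The submitters' processing notes name Agilent Feature Extraction and limma.

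From the scanner files, the log2 processed signal was reduced by the 75th percentile of the 59305 non-control spots of each array. Control spots were left out, as were spots marked as outliers by the scanner software unless all spots of a probe were, and spots of 1 probe were averaged, which gave 55681 probes. Probes were named by matching the accession in the files, without version, to a RefSeq gene table of the assembly GRCm38.p6. The array grid was annotated on mm9, so no coordinates are given. A symbol was found for 28026 probes (21154 genes), and the other probes kept the name in the files. A probe was kept where it was well above background on every array of at least 1 group, and of the kept probes of a gene the one with the highest mean over the 8 arrays stood for the gene. This left 24990 genes, of which 15658 had a symbol.

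Each gene was fitted with limma 3.58.1 in R 4.3.3, with a mean per group, 1 spread shared by all 8 arrays (5 residual degrees of freedom) and moderated variances. The contrasts were alphaD11 against the mean of the anti-V5 and naive means, alphaD11 against each control, and anti-V5 against naive. All tests were two-sided with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. For each of 22 gene lists, camera of limma was run with a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. Of these lists, 6 hold markers of other cell types that such a culture can contain (microglia and macrophages, oligodendrocyte lineage, neurons, endothelial and mural cells, fibroblasts and meninges, ependyma and choroid plexus). The extracellular matrix and fibroblast lists share 5 genes, the interferon and reactive astrocyte lists 4, and the astrocyte and glutamate lists 3. The groups, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined.

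For alphaD11 against both controls, the genes named are up to 15 higher and 15 lower ones with the largest log2 fold change among those past the threshold whose 4 alphaD11 arrays all lay on one side of all 4 control arrays. Up to 5 in each direction are named by that rule for the other contrasts, with the smallest p taking the place of size where no gene passed. RIKEN, predicted and clone names took no place. Ngf, Ntrk1, Ngfr, Sort1 and Bdnf are always named, and from each list the 4 members with the smallest p. A gene that was not well above background on any array of a group has only a bound there. It is written as at least so many fold, or as a bound where the gene did not pass. It sets the bright group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. Where a gene was well above background on 1 of the 4 arrays of a side, its other arrays there were treated alike and a bound is given too. Genes were named by fitted change, also where it rests on signal below background, so the names are not an order of measured folds. Bounds hold for the processed signal of the main setting, and normexp background correction gave smaller changes for some of these genes.

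The 75th percentile of the processed signal ran from 560 to 858 units, and 59.8% to 66.6% of probes per array were well above background, with 0 saturated spots. All 8 arrays lay on 1 slide and carried 1 scan time, so neither was a batch. The alphaD11 arrays lay in columns 1 and 2 of that slide, the naive arrays in column 3 and the anti-V5 arrays in column 4, so column and group cannot be told apart. Both rows of the slide held arrays of every group. The number of arrays limits the precision. On simulated data with the fitted variances of the 24990 genes, limma recovered 100% of genes changed by 2 on the log2 scale, 82.1% of those changed by 1 and 49.3% of those changed by 0.5 for alphaD11 against both controls. The shares in that order were 100%, 76.1% and 34.3% for alphaD11 against anti-V5, 98.5%, 76.1% and 25.4% for alphaD11 against naive, and 89.4%, 64.2% and 14.9% for anti-V5 against naive. A simulated list shifted by 0.5 passed camera (adjusted p = 1.15e-77, adjusted p = 4.92e-04 with an estimated correlation), and 0 of 100 unchanged lists did. In these simulations genes varied independently and few of them changed. In the data the estimated correlation within a list reached 0.374 and 13687 genes passed against both controls. The simulated shares and list results therefore need not hold for these data. The alternatives were quantile and median scaling, normexp background correction (offset 50, on the median spot signal because the mean is not in the files), no filter or a filter on all 8 arrays, the mean of a gene's probes, trended and robust variances, only the groups compared, blocks for replicate number and slide row, the authors' deposited values, array weights, an adjusted p of 0.10, and each sample left out.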

Results

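Gene expression was measured in primary astrocyte cultures, the star-shaped glial cells of the brain, after 24 hours with alphaD11, a monoclonal antibody that binds NGF and keeps it from its receptors. The question was which transcripts differ when NGF is neutralised, against 2 kinds of control: cultures given an antibody to V5, a peptide tag that mouse cells lack, and cultures given none. The series holds 4 alphaD11, 2 anti-V5 and 2 naive samples, each on 1 array with 33316 to 37091 probes well above background. Arrays of the alphaD11 group correlated with each other at r = 0.988 to 0.992 across genes, and with control arrays at 0.961 to 0.973. The anti-V5 and naive arrays correlated at 0.986 to 0.989. The 2 anti-V5 arrays correlated with each other at 0.993, and the 2 naive arrays at 0.982, below every pair of an anti-V5 and a naive array. The first principal component held 57.2% of the variance and separated the 4 alphaD11 arrays from the 4 controls. The median SD of a gene between replicates was 0.11 on the log2 scale in the alphaD11 group, 0.07 in the anti-V5 group and 0.11 in the naive group. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

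Against both controls, alphaD11 cultures had higher interferon-induced and microglial transcripts and lower transcripts of the cell cycle and the extracellular matrix. Ccl5, a chemokine that attracts T cells and monocytes, was 12.4-fold higher (log2 fold change 3.63 ± 0.04 SE, 4 alphaD11 against 4 control arrays, limma adjusted p = 2.1e-07). Cst7, a cysteine protease inhibitor of immune cells, was 36.4-fold higher (5.19 ± 0.06, adjusted p = 2.1e-07). Ccnb1, which encodes cyclin B1 and drives entry into mitosis, was 6.84-fold lower, with a log2 fold change of -2.77 ± 0.04 (adjusted p = 4.8e-07). Serpine1, the inhibitor of plasminogen activators, was 11.7-fold lower, with a log2 fold change of -3.54 ± 0.06 (adjusted p = 4.8e-07). In all, 13687 of 24990 genes passed the limma threshold, 7060 higher and 6627 lower, and 2485 of them changed by more than 2-fold. Signals of 13189 genes (52.8%) did not overlap between the 4 alphaD11 and the 4 control arrays, where chance gives 2.86%.

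**Figure D1:**
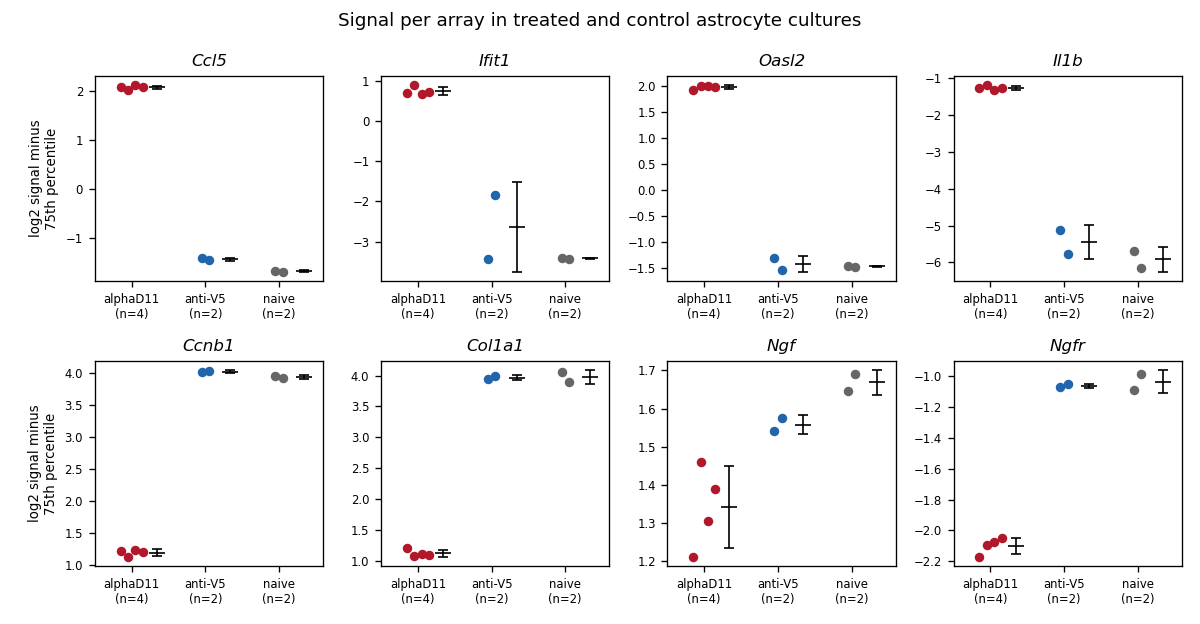
Each point is 1 array and gives the log2 processed signal minus the 75th percentile of that array (vertical axis) for alphaD11, anti-V5 and naive cultures (horizontal axis), and the bars are the mean and SD of each group (n = 4, 2 and 2). The alphaD11 arrays lie above all controls for Ccl5, Ifit1, Oasl2 and Il1b and below them for Ccnb1, Col1a1, Ngf and Ngfr.

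Among the 15 genes named by the size of their fitted rise, Ifit1 (3.77 ± 0.31), Oasl2 (3.41 ± 0.06) and Ifit3b (3.37 ± 0.06) encode antiviral proteins induced by interferons. The spread of Ifit1 came from the anti-V5 pair (-2.63 ± 1.12, SD, n = 2), whereas the alphaD11 arrays lay at 0.74 ± 0.10 (SD, n = 4). Il1b, the cytokine interleukin 1 beta, was well above background on 4 alphaD11 arrays and on 1 of the 4 control arrays, and was at least 17.3-fold higher (adjusted p = 2.4e-06). Cxcl13, a B cell chemokine, was well above background on 1 naive array but on neither anti-V5 array, and was at least 3.94-fold higher (adjusted p = 0.00634, and 0.0724 with the replicate number as a block, range over the alternatives 6.61e-06 to 0.0724). Gpr17, a receptor of the oligodendrocyte lineage, rose by 3.54 ± 0.06, and Gmnc, a regulator of multiciliated cells, by 3.40 ± 0.30. Slco1a4, an organic anion transporter, rose by 3.38 ± 0.11 and the methyltransferase gene Inmt by 4.25 ± 0.05. On its brightest probe Trim12a was not well above background in either control and was at least 42.2-fold higher in alphaD11 cultures (adjusted p = 4.8e-07). Another probe gave a log2 fold change of 4.15, below that bound, which is 5.40 on the log2 scale. Also not well above background in either control were Akr1c19, an aldo-keto reductase (at least 11.3-fold, adjusted p = 2.18e-05), the defensin Defb10 (at least 9.73-fold, adjusted p = 4.12e-06) and H2-Oa (at least 4.90-fold, adjusted p = 1.61e-06). A bound of this kind is the ratio to the lowest signal well above background. Fitted changes of such genes rest on signal below background, and 13 of the 15 genes stayed among the first 15 when ranked by their bounds. H2-Oa and Cxcl13 did not, and Usp18 and Ifit3 took their places.

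Among the 15 genes named by the size of their fitted fall, Col6a3, a chain of collagen VI, changed by -3.79 ± 0.13 and Tinagl1, a matrix protein, by -3.91 ± 0.10. Mmp12, the macrophage elastase, changed by -3.63 ± 0.18 and the caveolin gene Cav3 by -3.52 ± 0.18. Prl2c5, a prolactin-family growth factor linked to proliferation, changed by -5.66 ± 0.24 and was well above background on 3 of 4 alphaD11 arrays. Esam, an adhesion molecule of endothelial cells, changed by -3.85 ± 0.08 and was also measured on 3 of them, while Prph (at least 11.9-fold lower) and the matrilin gene Matn3 (at least 6.58-fold lower) were measured on 1. Nptx2, a neuronal pentraxin, was not well above background on any alphaD11 array and was at least 16.2-fold lower. Bounds for the other genes of this kind were at least 8.78-fold for the protease receptor F2rl1, at least 8.21-fold for the connexin gene Gjb3 and at least 6.76-fold for Cyp1a1, a target of the aryl hydrocarbon receptor. For Prss46 and Aoc1 they were at least 5.56-fold and at least 5.13-fold. Ranked by bounds, 9 of these genes stayed among the first 15, and Cyp1a1, Gjb3, F2rl1, Matn3, Prss46 and Aoc1 did not. The limma adjusted p of the 15 genes ran up to 5.27e-04. With normexp background correction the calls of Cyp1a1 (adjusted p = 0.242), Gjb3 (0.200), Aoc1 (0.668), F2rl1 (0.214), Prss46 (0.421) and Matn3 (0.297) were lost, while their adjusted p was at most 0.0114 in the other alternatives. Their log2 fold changes with normexp were -0.67, -0.66, -0.21, -0.59, -0.39 and -0.46 in that order. The bounds lay between -3.135 and -2.36 on that scale, so they do not hold under that correction.

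Interferon response genes rose together. Of 37 measured members, 35 were higher, 0 were lower and 2 did not pass, and 35 passed when adjusted over the list alone (median log2 fold change 1.55, camera adjusted p = 2.62e-18). Usp18, which removes the ubiquitin-like modifier ISG15, rose by 3.27 ± 0.06, Ifit3 by 3.19 ± 0.07 and the chemokine gene Cxcl10 by 2.53 ± 0.05. Markers of microglia and macrophages moved with this group: 21 of 28 were higher and 0 lower (22 adjusted over the list alone, median 0.83, camera adjusted p = 1.92e-07). Ly86 rose by 2.71 ± 0.08, Aif1, which encodes the microglial protein IBA1, by 1.66 ± 0.04, the invariant chain gene Cd74 by 1.61 ± 0.06 and the protease gene Ctss by 1.39 ± 0.05. Both lists also passed with an estimated correlation (adjusted p = 0.00604 for interferon and 0.0272 for microglia).

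Inflammatory cytokines and chemokines went both ways, with 15 of 27 higher and 9 lower (26 adjusted over the list alone), and as a list did not pass (median 0.31, camera adjusted p = 0.248). Saa3, an acute phase protein, rose by 3.12 ± 0.06 and the receptor gene Tlr2 by 2.03 ± 0.06, while Il11, a cytokine of the interleukin 6 family, changed by -3.42 ± 0.06. Reactive astrocyte genes did the same, with 18 of 37 higher and 14 lower (32 adjusted over the list alone, median 0.14, camera adjusted p = 0.508). The complement gene C3 rose by 2.85 ± 0.05, whereas Timp1, an inhibitor of metalloproteinases, changed by -2.35 ± 0.05 and the small heat shock protein gene Hspb1 by -1.78 ± 0.06. Microglia markers, with their median of 0.83, moved beside both lists.

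All 43 cell cycle genes were lower in alphaD11 cultures, and all 43 passed when adjusted over the list alone (median -2.27, camera adjusted p = 3.79e-25, adjusted p = 0.0247 with an estimated correlation). Ccnb2 changed by -2.49 ± 0.05, the mitotic kinase gene Plk1 by -2.61 ± 0.05 and Prc1, needed for cytokinesis, by -2.19 ± 0.04. Growth factor and MAPK response genes fell as a list, with 21 of 35 lower and 2 higher (25 adjusted over the list alone, median -0.36, camera adjusted p = 3.52e-05, adjusted p = 0.0272 with an estimated correlation). Vgf, which neurotrophins induce in neuronal cells, changed by -1.87 ± 0.04, Arc by -1.70 ± 0.09, Ier3 by -1.04 ± 0.05 and Fosl1, a subunit of AP-1, by -0.99 ± 0.05. Fibroblast and meningeal markers (14 of 24 lower, median -0.63) and endothelial and mural markers (10 of 18 lower, median -0.44) fell beside this list.

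Extracellular matrix genes fell, with 32 of 45 lower and 6 higher (39 adjusted over the list alone, median -1.01, camera adjusted p = 1.07e-09, adjusted p = 0.0247 with an estimated correlation). Col1a1, a chain of collagen I, changed by -2.85 ± 0.06, the basement membrane gene Nid1 by -2.31 ± 0.05 and Lamb1, a laminin chain, by -1.96 ± 0.04. Fibroblast and meningeal markers moved with them, with 14 of 24 lower and 6 higher (20 adjusted over the list alone, median -0.63, camera adjusted p = 0.0259, adjusted p = 0.110 with an estimated correlation). Aldh1a2, which makes retinoic acid in the meninges, changed by -2.52 ± 0.07 and Mfap5 by -1.43 ± 0.05, while Ogn rose by 1.27 ± 0.05. Endothelial and mural markers fell in the same test, with 10 of 18 lower and 2 higher (12 adjusted over the list alone, median -0.44, camera adjusted p = 0.0216, adjusted p = 0.110 with an estimated correlation). Among them Cdh5, the endothelial cadherin, changed by -1.86 ± 0.08 and Acta2, smooth muscle actin, by -1.22 ± 0.04, while Slco1a4 rose by 3.38 ± 0.11. With normexp background correction, the filter on all 8 arrays and the authors' values, the fibroblast list (adjusted p = 0.155, 0.135 and 0.130, range over the alternatives with camera 0.0138 to 0.155) and the endothelial list (0.0684, 0.109 and 0.110, range 0.00193 to 0.110) did not pass. With fry, which tests against no change and not against other genes, their adjusted p were 1.41e-06 and 9.31e-07. With normexp the fibroblast median was -0.03, and -0.20 relative to the median of all genes, and with the authors' values the endothelial median was -0.24. Normexp also ended the call of Cdh5 (0.155, at most 0.00449 in the others).

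Astrocyte markers rose with the preset correlation, with 22 of 30 higher and 4 lower (26 adjusted over the list alone, median 0.52, camera adjusted p = 1.35e-04, adjusted p = 0.165 with an estimated correlation). Ndrg2 was 2.84-fold higher (SE 0.07 on the log2 scale), Ntsr2 rose by 1.49 ± 0.07 and the glycolytic enzyme gene Aldoc by 1.36 ± 0.05. Hes5, a target of Notch in neural progenitors, changed by -2.09 ± 0.06. Ependymal and choroid plexus markers rose in the same way, with 14 of 21 higher and 3 lower (17 adjusted over the list alone, median 0.80, camera adjusted p = 7.93e-04, adjusted p = 0.0573 with an estimated correlation). Dynlrb2, Cfap126, Enkur and Tekt1, all parts of motile cilia, rose by 1.59 ± 0.05, 1.58 ± 0.06, 1.26 ± 0.06 and 1.18 ± 0.04. Oligodendrocyte lineage markers did not pass as a list, with 9 of 19 higher and 4 lower (13 adjusted over the list alone, median 0.31, camera adjusted p = 0.0622, range over the alternatives with camera 0.00604 to 0.165). Against anti-V5 alone this list passed (camera adjusted p = 0.0302, and 0.117 with an estimated correlation). Of these, Bcas1 rose by 1.99 ± 0.06, Cldn11 by 1.71 ± 0.05 and the myelin gene Mag by 1.46 ± 0.07. Neuron markers did not pass either, with 4 of 20 higher and 8 lower (12 adjusted over the list alone, median -0.17, camera adjusted p = 0.308). Among them were Syt1 (1.06 ± 0.09), Dcx (-1.75 ± 0.12, above background on 2 of 4 alphaD11 arrays), Rbfox3 (-1.09 ± 0.06) and Npy (-0.60 ± 0.06). With normexp background correction the calls of Dcx (adjusted p = 0.944) and Rbfox3 (0.692) were lost, while their adjusted p was at most 0.00511 in the other alternatives.

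**Figure D2:**
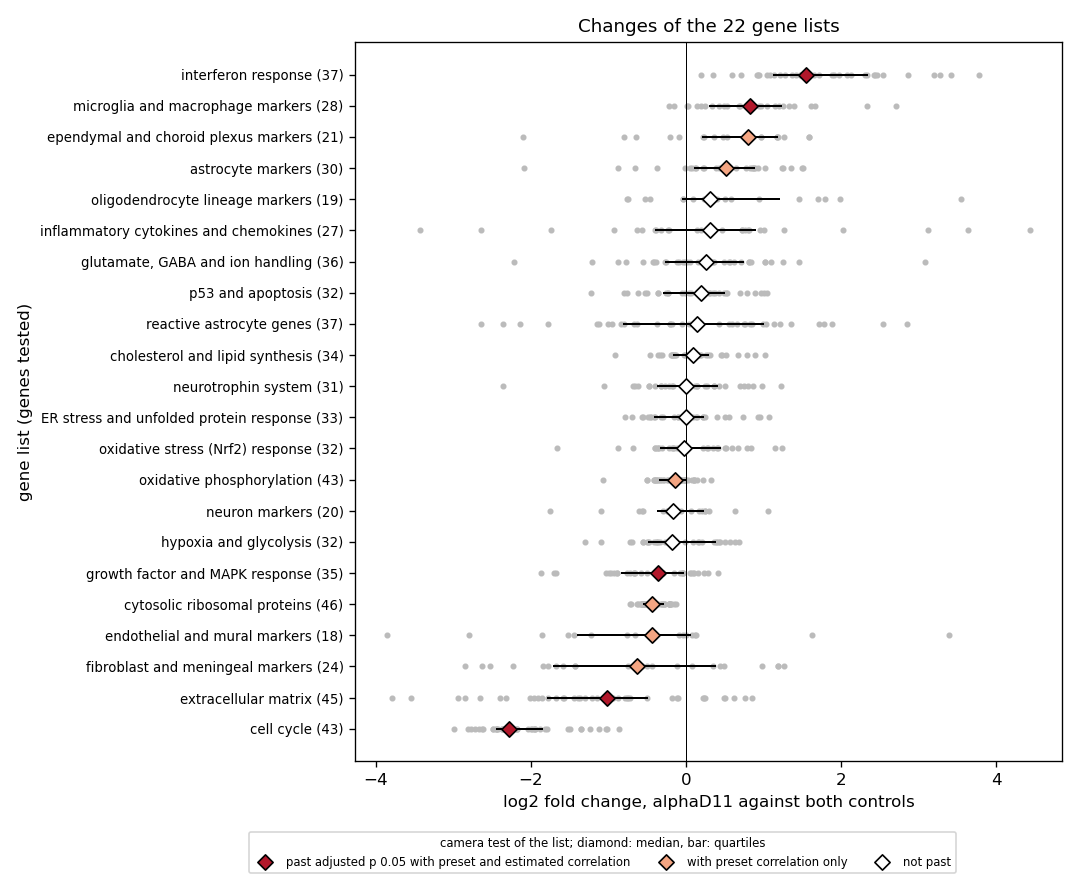
The horizontal axis gives the log2 fold change of alphaD11 against both controls and the vertical axis the 22 gene lists with the number of genes tested, where grey points are genes, diamonds medians and bars the quartiles. The medians run from -2.27 for cell cycle genes to 1.55 for interferon response genes.

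Ribosomal protein genes were lower, with 43 of 46 lower and 0 higher (44 adjusted over the list alone, median -0.43, camera adjusted p = 3.09e-12, adjusted p = 0.187 with an estimated correlation), and their median was -0.21 with quantile scaling. Rpl8 changed by -0.71 ± 0.04 and Rpl18 by -0.72 ± 0.05, as did Rpl12 (-0.58 ± 0.05) and Rps6 (-0.57 ± 0.04), of which another probe gave 0.38. Oxidative phosphorylation genes had 16 of 43 lower and 2 higher (18 adjusted over the list alone, median -0.14, camera adjusted p = 0.00632, adjusted p = 0.395 with an estimated correlation). With quantile scaling their direction turned (median 0.03, adjusted p = 0.892, range over the alternatives 1.21e-07 to 0.892). Cycs, which encodes cytochrome c, changed by -1.07 ± 0.06 on its brightest probe and by 0.61 on another, and Cyc1 (-0.50 ± 0.05), Atp5g1 (-0.50 ± 0.05) and Atp5o (-0.38 ± 0.04) were lower.

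The other lists held members in both directions and did not pass as lists in the main setting. Glutamate, GABA and ion handling had 17 of 36 higher and 10 lower (27 adjusted over the list alone, median 0.26, camera adjusted p = 0.140, range over the alternatives with camera 0.0409 to 0.288). Gria1, a glutamate receptor subunit, rose by 3.08 ± 0.08, the potassium channel genes Kcnj10 and Kcnj16 by 1.46 ± 0.06 and 1.02 ± 0.05, and Glul, glutamine synthetase, by 1.25 ± 0.06. The p53 and apoptosis list had 15 of 32 higher and 8 lower (23 adjusted over the list alone, median 0.20, camera adjusted p = 0.250). In it Trp53inp1 (1.05 ± 0.08), Sesn1 (1.00 ± 0.07), Bbc3 (0.97 ± 0.06) and Fas (0.90 ± 0.05) were higher. Cholesterol and lipid synthesis had 12 of 34 higher and 8 lower (20 adjusted over the list alone, median 0.10, camera adjusted p = 0.381). The desaturase genes Scd1 (1.01 ± 0.06) and Scd2 (0.89 ± 0.05), Tm7sf2 (0.78 ± 0.05) and Fasn (0.51 ± 0.06) were higher. Hypoxia and glycolysis had 10 of 32 higher and 15 lower (28 adjusted over the list alone, median -0.18, camera adjusted p = 0.288, range over the alternatives with camera 0.0257 to 0.892). Ankrd37 (-1.30 ± 0.06), Adm (-1.10 ± 0.06) and Car9 (-0.69 ± 0.05) were lower and P4ha1 was higher (0.69 ± 0.04). The Nrf2 list had 13 of 32 higher and 11 lower (24 adjusted over the list alone, median -0.03 but mean 0.06, camera adjusted p = 0.934, with a median of 0.12 after quantile scaling). Osgin1 (1.23 ± 0.07), Gstm1 (1.14 ± 0.07) and Gsta4 (0.79 ± 0.06) were higher and Txnrd1 was lower (-0.68 ± 0.06). ER stress and unfolded protein response genes had 8 of 33 higher and 11 lower (19 adjusted over the list alone, median -0.0049 but mean 0.01, camera adjusted p = 0.807, with a median of 0.05 after quantile scaling). Chac1 (1.07 ± 0.06), Ddit3 (0.96 ± 0.05) and Herpud1 (0.93 ± 0.05) were higher and the chaperone gene Hsp90b1 was lower (-0.57 ± 0.05).

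The neurotrophin system, to which the antibody's target belongs, had 12 of 31 members higher and 13 lower (27 adjusted over the list alone, median 0.0043 but mean -0.01, camera adjusted p = 0.934, with a median of -0.03 after median scaling). Ngf itself stood at 1.34 ± 0.11 (SD, n = 4) in alphaD11 cultures, 1.56 ± 0.02 (n = 2) with anti-V5 and 1.67 ± 0.03 (n = 2) in naive cultures, a log2 fold change of -0.27 ± 0.06 SE against both controls (limma adjusted p = 0.0101). With the replicate number as a block it did not pass (adjusted p = 0.0902, range over the alternatives 0.00448 to 0.0902). Ngfr, the p75 receptor of all neurotrophins, was 2.07-fold lower, with a change of -1.05 ± 0.05 (adjusted p = 6.38e-06), and Bdnf changed by -0.47 ± 0.06 (adjusted p = 4.09e-04). Ntf3, neurotrophin 3, rose by 1.22 ± 0.07 and the adaptor gene Sh2b2 by 0.98 ± 0.07. Sort1, the co-receptor sortilin, was higher by 0.50 ± 0.05 on its brightest probe (adjusted p = 2.01e-04), while the 2 other probes gave -0.30 and 0.23, and the mean of its probes did not pass (0.14, adjusted p = 0.0794, range over the alternatives 3.06e-05 to 0.0794). The probe of Ntrk1, the high-affinity NGF receptor, was not well above background on any array.

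Sex-linked transcripts, looked at after the data were seen, moved with the same split of the samples. The Y-linked genes Ddx3y, Eif2s3y and Uty were higher in alphaD11 than in control cultures by 1.15 ± 0.11, 1.14 ± 0.05 and 1.27 ± 0.08, Uty being well above background on 1 of 2 anti-V5 arrays (limma adjusted p = 1.39e-04, 6.68e-06 and 2.07e-05). Xist, expressed from the inactive X of female cells, changed by -0.91 ± 0.19 (adjusted p = 0.00562). Between anti-V5 and naive cultures these genes differed by 0.04 ± 0.15, 0.16 ± 0.08, -0.13 ± 0.11 and 0.02 ± 0.27, and none passed. The labels give every sample as pooled male and female.

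**Figure D3:**
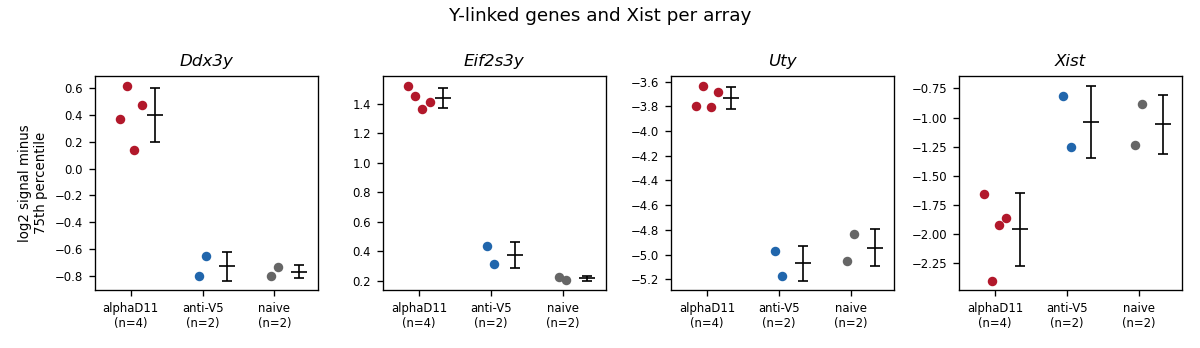
Each point is 1 array and gives the log2 processed signal minus the 75th percentile of that array (vertical axis) for alphaD11, anti-V5 and naive cultures (horizontal axis), with the mean and SD of each group (n = 4, 2 and 2). The 3 Y-linked genes lie higher and Xist lower in the alphaD11 arrays than in both kinds of control.

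Against the anti-V5 cultures alone, which had received an antibody of another target at the same concentration, the same groups stood out: interferon genes were higher (34 of 37, median 1.49, camera adjusted p = 4.87e-20) and cell cycle genes lower (43 of 43, median -2.27, camera adjusted p = 2.94e-26). Microglia markers were higher in 18 of 28 (median 0.83, camera adjusted p = 5.48e-08) and matrix genes lower in 33 of 45 (median -1.03, camera adjusted p = 5.64e-10), and these 4 lists also passed with an estimated correlation. In all 12 lists passed, 6 of them with an estimated correlation. Adjusted over the list alone, 35, 43, 20 and 39 members of them passed. By fitted change the rises named were in Trim12a (at least 43.7-fold on its brightest probe, a log2 fold change of 3.90 on another), Defb10 (at least 10.1-fold), Cxcl13 (at least 6.04-fold), Cst7 (5.24 ± 0.07) and Inmt (4.26 ± 0.06), where a bound stands for a gene not well above background with anti-V5. The falls named in this way were in Col25a1 (at least 120-fold), Nptx2 (at least 14.4-fold), Prss46 (at least 7.38-fold), Cyp1a1 (at least 7.32-fold) and Prl2c5 (-5.58 ± 0.30). Ranked by bounds, 3 of the 5 rises and 3 of the 5 falls kept a place, while Defb10, Cxcl13, Prss46 and Cyp1a1 did not. Col25a1, a neuronal collagen, stood at 1.11 ± 4.71 (SD, n = 2) with anti-V5 and was not well above background in naive cultures, and its bound was at least 11.9-fold without anti-V5 replicate 2 and at least 1210-fold without replicate 1. The bound of Prss46 was at least 4.92-fold and at least 11.1-fold in the same cases. With normexp background correction the calls of Col25a1 (adjusted p = 0.105), Nptx2 (0.0855), Cyp1a1 (0.331) and Prss46 (0.372) were lost, and with the replicate number as a block that of Cxcl13 (0.0627). With normexp, Col25a1, Nptx2, Cyp1a1 and Prss46 changed by -3.44, -1.18, -0.75 and -0.61, against bounds of -6.90, -3.85, -2.87 and -2.88 on the log2 scale. In all 11827 genes passed the limma threshold, 5724 higher and 6103 lower. Ngfr (-1.04 ± 0.06, adjusted p = 2.57e-05) and Bdnf (-0.50 ± 0.07, adjusted p = 0.00111) were lower and Sort1 higher (0.44 ± 0.06, adjusted p = 0.00133, but 0.176 for the mean of its probes). Ngf did not pass (-0.22 ± 0.08, adjusted p = 0.0597). It passed when alphaD11 replicate 2 was left out (-0.26, adjusted p = 0.0277), and also with trended and robust variances and with array weights.

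Against the naive cultures alone, 35 of 37 interferon genes (median 1.64, camera adjusted p = 6.17e-19) and 19 of 28 microglia markers (median 0.83, camera adjusted p = 2.16e-07) were higher. Cell cycle genes were lower in 42 of 43 (median -2.23, camera adjusted p = 1.61e-27) and matrix genes in 32 of 45 (median -1.06, camera adjusted p = 2.29e-10), and these 4 lists also passed with an estimated correlation. In all 11 lists passed, 5 of them with an estimated correlation. Adjusted over the list alone, 35, 20, 43 and 39 members of them passed. Trim12a (at least 40.7-fold on its brightest probe, a log2 fold change of 4.40 on another), Il1b (at least 18.4-fold), Akr1c19 (at least 10.9-fold), Defb10 (at least 9.40-fold) and Cst7 (5.13 ± 0.07) were the rises named by fitted change. Nptx2 (at least 18.1-fold), the olfactory receptor gene Olfr140 (at least 12.6-fold), Cyp1a1 (at least 6.24-fold), Prl2c5 (-5.74 ± 0.30) and the defensin Defb29 (at least 26.2-fold) were the falls. Ranked by bounds, 3 of the 5 rises and 3 of the 5 falls kept a place, while Akr1c19, Defb10, Olfr140 and Cyp1a1 did not. Neither Olfr140 nor Defb29 was well above background with anti-V5, and Defb29 was on 1 of 4 alphaD11 arrays. The bound of Olfr140 was at least 77.4-fold without naive replicate 1 and at least 2.04-fold without naive replicate 2, and Defb29 did not pass without naive replicate 1 (adjusted p = 0.0713). The bound of Defb29 was at least 15.5-fold without naive replicate 1, at least 44.0-fold without naive replicate 2 and at least 41.2-fold without alphaD11 replicate 3. With normexp background correction the calls of Olfr140 (0.947), Defb29 (0.0974) and Cyp1a1 (0.394) were lost, and with the replicate number as a block that of Olfr140 (0.122). With normexp, Olfr140, Defb29 and Cyp1a1 changed by -0.05, -1.25 and -0.59, against bounds of -3.65, -4.71 and -2.64 on the log2 scale. In all 12093 genes passed the limma threshold, 6470 higher and 5623 lower. Ngf was lower (-0.33 ± 0.08, adjusted p = 0.0127), but not past the threshold without naive replicate 2 (adjusted p = 0.0639), with normexp (0.0644) or with the replicate number as a block (0.0927). Ngfr (-1.06 ± 0.06, adjusted p = 2.26e-05) and Bdnf (-0.45 ± 0.07, adjusted p = 0.00175, 0.0509 with that block) were lower and Sort1 was higher (0.57 ± 0.06, adjusted p = 4.01e-04, but 0.127 for the mean of its probes).

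The genes called against each control overlapped: 5184 were higher and 5126 lower against both anti-V5 and naive cultures, and 3 went opposite ways. The same 4 alphaD11 arrays entered both comparisons. Simulated data with no effect gave 0 shared calls in each direction on average over 20 draws, and independent lists of these sizes would share 1482 and 1373. Neither figure measures what the shared arrays add when they differ from the controls. Data with no effect yield few calls at all, and independent lists leave the sharing out. With alphaD11 replicates 1 and 2 set against anti-V5 and replicates 3 and 4 against naive, 4257 genes were higher and 4237 lower in both.

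Anti-V5 and naive cultures were set against each other to see what an antibody of another target does by itself, and no gene passed. The limma count was 0 of 24990 at adjusted p 0.05 and 0 at adjusted p 0.10, with 1310 genes at an unadjusted p under 0.05, where chance gives 1250. Quantile scaling gave 2 genes and the slide row as a block gave 1. Ngf (-0.11 ± 0.09), Ngfr (-0.02 ± 0.07), Bdnf (0.05 ± 0.08) and Sort1 (0.13 ± 0.07) had limma adjusted p from 0.812 to 0.967. The smallest p belonged to Phyhipl (0.79 ± 0.07), Zfp296 (0.67 ± 0.07), Ankrd2 (bound 2.87-fold higher), Amy2a5 (bound 1.45-fold higher, with another probe at a log2 fold change of -0.44) and Prrt2 (0.40 ± 0.07) in one direction. In the other they belonged to Tas1r2 (bound 4.64-fold lower), Hsd17b6 (bound 4.32-fold lower), Olfr531 (bound 1.73-fold lower), Olfr406 (bound 1.31-fold lower) and Rad9b (-0.47 ± 0.09). None of these genes passed, so the bounds are not minimum changes, and that of Ankrd2 equalled its fitted fold. The adjusted p of these genes ran from 0.164 to 0.812. Phyhipl, Zfp296 and Olfr406 were well above background on 1 of 2 naive arrays and Rad9b on 1 of 2 anti-V5 arrays. Leaving out 1 sample brought Phyhipl past the threshold in each of 4 cases (adjusted p from 0.0166 to 0.0449), Olfr531 without anti-V5 replicate 1 (0.0318) or either naive replicate (0.0203 and 0.0248). Hsd17b6 passed without either naive replicate (0.0141 and 0.00257). Without naive replicate 2 the same held for Tas1r2 (0.0101) and Ankrd2 (0.0109). Ribosomal protein genes (median 0.10, camera adjusted p = 0.00138) and oxidative phosphorylation genes (median 0.09, camera adjusted p = 0.00919) were higher with anti-V5 at the preset correlation, with 0 single members past the threshold, also when adjusted over the list alone, and adjusted p = 0.885 for each list with an estimated correlation. Neither list passed without anti-V5 replicate 1, without naive replicate 1 or without naive replicate 2. The other 20 lists did not pass. The count of genes rose to 85, 47, 172 and 270 when anti-V5 replicate 1, anti-V5 replicate 2, naive replicate 1 or naive replicate 2 was left out.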

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

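All tests of explanations below except the count of other splits of the samples were chosen after the results were seen. In the group of 4 alphaD11 arrays, 125 named genes and 4 array measures were screened for an array lying apart from the others by Dixon's test, which picks out about 1 in 20 groups by chance (6.45 of 129), and 4 were found. Inmt stood at 0.83 in alphaD11 replicate 1, against 0.94 to 0.96 in the others, and Ntsr2 in the same replicate at 2.18, against 2.38 to 2.41. Il11 stood at -4.53 in alphaD11 replicate 4, against -4.41 to -4.38, and Ntf3 at -2.73 in alphaD11 replicate 3, against -2.57 to -2.54. These gaps are small beside the changes of the 4 genes against the controls.

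For the 13687 genes past the threshold between alphaD11 and control cultures, chance spread between single arrays is an unlikely cause. Of the 35 splits of the 8 arrays into 4 and 4, with the controls as 1 group, the real split gave 13806 genes and the highest of the others gave 0. Those other splits mix alphaD11 with control arrays, so a real difference enters their spread and keeps their counts low. The count also cannot address chance differences between cultures or pools of pups. Spike-in RNA, the same in every sample, argues against the position of the arrays on the slide as the whole cause for bright probes. Over 7 of the 10 spike-ins the alphaD11 minus control difference had an SD of 0.03, once the shift common to them was taken out. That is 0.0431 of the SD of 0.69 across genes. Their mean level relative to the 75th percentile ran from 2.04 in alphaD11 replicate 2 to 3.61 in replicate 3 (SD over the 8 arrays 0.47). Each spike-in value averaged all its spots, nearly all well above background. Part of the low ratio may come from that, and dim probes are not covered. A different share of male cells, which the Y-linked genes and Xist may reflect, cannot be the whole cause, since 984 genes past the threshold moved by over 2 standard errors more than the largest Y-linked rise (1.27) or the lowest Xist probe (-1.37). The 3 Y-linked genes rose by 1.15, 1.14 and 1.27 while the 2 Xist probes changed by -0.91 and -1.37, and none of these genes passed between the controls. These values argue against groups with the same share of male cells that differ by the antibody alone. Separate pools of pups, which the Y-linked rise of 1.19 on average may reflect, could also differ in density or cell makeup. Their effect and that of the antibody stay open and were not tested, since the design gives no way to separate them.

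Interferon response genes and microglia markers rose together. A larger share of microglia as the whole cause of the interferon rise would lift interferon genes by no more than markers found only in microglia. The interferon median lay 0.72 above the microglia marker median (95% bootstrap interval over genes 0.42 to 1.38). The medians cannot decide this, since the markers varied (SD 0.70) and those also expressed by other cells would rise less. A lower share of astrocytes with every other cell type gaining alike would raise their markers alike. The microglia median instead exceeded the fibroblast median by 1.46 (0.64 to 2.45, and 0.74, 0.27 to 1.37, with normexp background correction). This cannot address astrocytes replaced by 1 other cell type, and 22 of 30 astrocyte markers were higher and 4 lower. Endotoxin in the antibody preparation cannot be told apart from an effect of NGF neutralisation, since the median change of the inflammatory list, 0.31, had an interval (-0.32 to 0.80) that spans 0 and no endotoxin measure is at hand. A larger share of microglia or of a subset of them stays open, since 4 of 28 markers rose as far as the median interferon gene. That, an interferon response to the treatment, one in activated microglia, or a difference between pools of pups may each account for the pattern.

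All 43 cell cycle genes were lower in alphaD11 cultures. A loss of fibroblast-like cells could lower them at most as far as markers found only in those cells. The cell cycle median lay below the fibroblast median (by -1.65, 95% bootstrap interval over genes -2.35 to -0.59, against an SD of 1.28 between the markers, of which 14 of 24 were lower and 6 higher). With markers so mixed, the medians cannot decide whether such a loss is the whole cause. The scaling does not account for the fall of the cell cycle genes, since their highest median under another scaling was -2.10. A loss of fibroblast-like cells or of a subset of them stays open, since 3 of 24 markers, Col1a1 (-2.85) and Aldh1a2 (-2.52) among them, fell as far as the median cell cycle gene. Slower division after NGF neutralisation and a difference in density or age between the cultures both stay open and were not tested.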

How the results depend on the processing

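No test in this part was chosen after the results were seen. Of 2994 recomputed values of named genes, 28 lost and 15 gained a call and 0 turned, and of 484 list values 12 lost and 18 gained a call and 1 turned (oxidative phosphorylation with quantile scaling, adjusted p = 0.892, range over its alternatives 1.21e-07 to 0.892). The causes were not tested except where stated. Normexp background correction moved the median of all genes to 0.17 (cell cycle genes relative to it, -2.27) and ended 17 of the named calls. It called 9271 genes against both controls, where the main setting called 13687, and 7297 against anti-V5 and 7436 against naive. With the replicate number as a block the counts were 8399 against both controls, 6643 against anti-V5 and 6676 against naive. Only replicates 1 and 2 of alphaD11 then inform the contrasts, and same-numbered arrays did not deviate together (correlations -0.20 to 0.08), so the numbers pair nothing here. The anti-V5 against naive count was 2 with quantile scaling, 1 with the slide row as a block and 0 in the other settings with all samples. Leaving out 1 sample at a time gave 12082 to 13796 genes against both controls, 8673 to 12315 against anti-V5, 9780 to 12274 against naive and 0 to 270 between the controls. It gave 11 to 12 lists and 30 of the named genes, and a lone sample is assumed to vary like the other groups. Of the 22 lists 11 passed, against 5 with an estimated correlation and 20 with fry, which asks whether a list moves and not whether it moves more than other genes. Of the 30 named genes, 14 had a value and kept their call in the authors' deposited values and 14 with the filter on all 8 arrays, since both leave out dim probes. Signal over background limits the fold changes of genes dim in a group or on 3 of 4 arrays of a side, which are given as bounds.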

Other observations

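All tests in this part were chosen after the results were seen. Further gene groups were compared between alphaD11 and both controls. They were picked with the results in view, so their p-values are not independent evidence that they moved. Of 22 genes for class I antigen presentation and complement, 20 were higher and 1, C2, was lower (median 1.15, camera adjusted p = 3.89e-10, adjusted p = 0.0135 with an estimated correlation), of which 10 belong to lists already described. The complement gene C1ra rose by 2.20 ± 0.05 SE and the class I gene H2-K1 by 1.42 ± 0.04, and Cfb, not well above background in either control, was at least 2.29-fold higher. The list holds C1qa, C1qb and C1qc, which are also among the microglia and macrophage markers, and 21 of 28 of those markers were higher (median 0.83). Of 20 actin cytoskeleton and contractile genes, 19 were lower and 0 higher (median -0.76, camera adjusted p = 2.82e-09, adjusted p = 0.0201 with an estimated correlation), with Tagln at -0.66 ± 0.09 and Cnn1 at -0.58 ± 0.06. Acta2 and Tagln are also among the endothelial and mural markers, of which 10 of 18 were lower (median -0.44), and 14 of 24 fibroblast and meningeal markers were lower (median -0.63). Of 21 DNA repair and replication fork genes, 20 were lower and 0 higher (median -1.64, camera adjusted p = 1.28e-13, adjusted p = 0.0121 with an estimated correlation), with Exo1 at -2.11 ± 0.06 and Rad51 at -1.65 ± 0.05. All 43 cell cycle genes fell beside them (median -2.27), so this group need not be a change apart from that list. Lysosomal genes did not pass as a list, with 12 of 24 higher and 3 lower (median 0.15, camera adjusted p = 0.0584).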
